A study of Mus musculus with 12 samples.

How the data were processed

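RNA was sequenced from mouse embryonic stem cells (129P2/OlaHsd) carrying a doxycycline-inducible Mesp1, a transcription factor of early cardiac and pharyngeal mesoderm. The labels describe serum-free embryoid bodies that were dissociated and replated as a monolayer. All 4 groups received doxycycline (500 ng/ml), starting on day 5. BMP4 (20 ng/ml) was given from the same day for the cardiac condition and left out for the skeletal myogenic condition. Cells were collected at day 6 (early) or day 12 (late), which gives 4 groups of 3 libraries, here named early_SKM and early_CM at day 6 and late_SKM and late_CM at day 12. SKM stands for the condition without BMP4 and CM for the condition with BMP4. Total RNA was column-purified with DNase treatment and made into TruSeq RNA v2 libraries. The labels do not state that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between samples.

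The authors deposited one table of TPM values (a gene's share of a library's transcripts, scaled to a fixed total), with 20308 gene symbols and 1 column per library. Their notes name CASAVA 1.8.2, RSEM 1.2.3, Bowtie 0.12.9 and the mouse build mm10, and do not state the annotation, the read length or any filter. Every column had the same total within rounding, as the unit requires, so the values carry no library depth. The depth is unknown, and no counting intervals or detection limits are given. No further normalization between libraries was added for the results reported first. Of the symbols, 19325 (95.2%) were found in GENCODE mouse release 21, from which the coordinates were taken (53 of 54 genes looked up, Spink3 being absent under that symbol).

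Genes with at least 1 TPM in at least 3 of the 12 libraries were kept, which left 13837 genes, while 2078 genes were at 0 in all libraries. The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 mean per group, a spread shared by the 4 groups and eBayes with a trend. The contrasts were BMP4 against none at day 6, BMP4 against none at day 12, day 12 against day 6 without BMP4, day 12 against day 6 with BMP4, and the difference between the BMP4 effects of the days (the interaction). All p-values were two-sided and adjusted by Benjamini-Hochberg over the tested genes within a comparison, and a gene was called at an adjusted p under 0.05. Log2 differences are fitted values on log2(TPM + 1) with their standard error (SE), and levels are means of TPM with the standard deviation (SD) of 3 libraries.

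Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, over lists with at least 4 tested members and with Benjamini-Hochberg adjustment over the 31 lists within a comparison. The lists covered cardiac and skeletal muscle genes, signalling responses, mesodermal and other cell types, cell state, and genes of constant use. Camera was also run with an estimated correlation, and fry as a test of whether a list's genes moved one way on balance. Each list's members were also counted after adjustment over the list alone. The groups, the test, the filter, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. That rule took a panel of 19 genes, the 6 called genes with the highest and the 6 with the lowest log2 difference per comparison (4 and 4 for the interaction), and the most changed called members of each list. The 6 and 6 also needed a mean of at least 10 TPM in the higher group and no overlap between the 3 libraries of either group, which chance gives for 10% of genes. Predicted loci were left out of that choice. Tbx5 and Myf5 of the panel did not pass the filter and were not tested.

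Replicate numbers are shared by the 4 groups, and the labels give the same experiment code to libraries of the same number without saying what it marks. Whether the numbers pair the libraries was checked from the deviations from the group means. At day 6 the same-numbered libraries with and without BMP4 deviated together across genes (r = 0.338, 0.400 and 0.185 for numbers 1, 2 and 3), and at day 12 as well (r = 0.616, 0.429 and 0.569). The numbers therefore pair the libraries within a day. Across genes, which are not independent replicates, these r values describe likeness only. A fit with a replicate block within each day was added for the BMP4 comparisons and the interaction after the data were seen.

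Data simulated with the spread of the 4 groups, and without the pairing of same-numbered libraries, were used to test the method. Of 13837 genes, 100 were shifted by 1 log2 unit and 100 by 2 in each draw. The share of false calls depends on how many genes change, so the shares below hold for this setting only. At day 6, 74.6% of genes shifted by 1 log2 unit and 94.0% of those shifted by 2 were recovered, with 0.343% of calls false. At day 12 the shares were 73.2% and 90.4%, with 26.3% of calls false, where the fit shared 1 spread although libraries of day 12 varied more than those of day 6 (root mean square SD 0.417 against 0.239 on the log2 scale). Library weights by day gave 7.65% false calls at day 12 and recovered 57.2% and 85.8%. A simulation added after the data were seen let same-numbered libraries share part of their deviation (r = 0.308 at day 6 and 0.538 at day 12). At day 12 the shared spread then gave 2.5005% false calls, library weights by day 0.294% and the block within each day 10.7%. For lists, the shifted list was called in 5 of 5 simulated draws at each day, and 2 of the other lists were called over 5 draws of 29 lists.

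Other settings changed the pseudocount (0.1 or 5), the filter (none, or at least 5 TPM), the scaling (median of ratios, quantile normalization), the variance model, the libraries in the fit, the replicate block, the threshold and the list test. Each of the 12 libraries and each of the 3 replicate numbers was also left out in turn. Added after the data were seen were library weights by day, the block within each day, fits on the libraries of 1 comparison with a block, and fits without the BMP4 libraries numbered 3. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0 was used by limma. No library was left out of the results reported first. Sequence reads were not analysed here.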

Results

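Gene expression was measured by RNA sequencing in derivatives of Mesp1-induced cardiopharyngeal mesoderm grown from mouse embryonic stem cells. The 12 libraries formed 4 groups of 3, at day 6 and day 12 and with or without BMP4. Each library listed between 12385 and 12629 genes at 1 TPM or more at day 6 and between 13063 and 13454 at day 12. The translation factor gene Eef1a1 was the most abundant in every library, at 13706 to 19102 TPM, and the 10 most abundant genes held 6.06% to 8.41% of a library's total. Libraries of a group correlated across genes at r of 0.988 to 0.995 in early_SKM, 0.980 to 0.992 in early_CM, 0.965 to 0.971 in late_SKM and 0.955 to 0.958 in late_CM. The first principal component held 54.1% of the variance and the second 16.5%. Mesp1, the induced factor (chromosome 7, 79792241 to 79793788 on mm10), was at 10.5 ± 0.914 TPM (mean ± SD, n = 3) in early_SKM and 8.65 ± 2.56 TPM in early_CM. It was at 0.577 ± 0.536 TPM in late_SKM and 0.333 ± 0.119 TPM in late_CM.

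**Figure D1:**
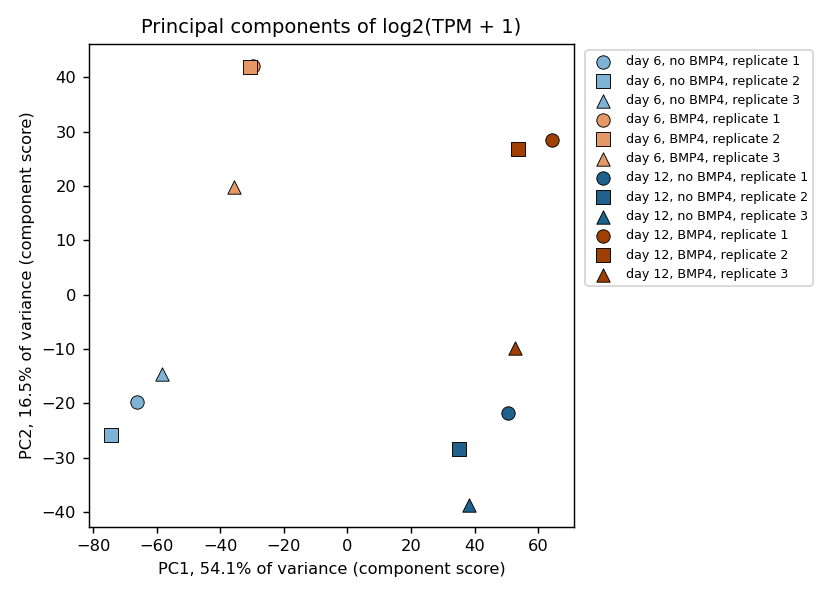
Principal components of log2(TPM + 1) over the tested genes, 1 point per library, with component 1 (54.1% of the variance) on the horizontal axis and component 2 (16.5%) on the vertical axis. Colours mark the 4 groups and symbols the replicate.

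The first question was what BMP4 changed after 1 day of treatment, at day 6. Direct BMP targets rose. Id1, an inhibitor of helix-loop-helix transcription factors (chromosome 2, 152736251 to 152737410), was at 4.39 ± 2.43 TPM (mean ± SD, n = 3) without BMP4 and 185 ± 30.8 TPM with it. The log2 difference was 5.20 ± 0.36 (SE). Several cardiac genes rose with it, while the cardiac actin gene Actc1 was lower with BMP4 (3714 to 4248 against 5855 to 9983 TPM, not called). The atrial myosin light chain gene Myl7 (chromosome 11, 5896637 to 5898782) went from 6.82 ± 1.18 to 949.6 ± 648 TPM. Hand1, a cardiac transcription factor (chromosome 11, 57828705 to 57832818), went from 1.44 ± 0.520 to 184 ± 134 TPM. Genes of the presomitic and somitic mesoderm fell. Ripply2, a repressor at the forming somite border (chromosome 9, 87015537 to 87019917), was at 64.4 ± 30.1 TPM without and 0.767 ± 0.692 TPM with BMP4. Dll3, a Notch-pathway gene of somite segmentation, was at 517 ± 63.2 and 20.6 ± 22.6 TPM (7.55 TPM without early_CM 3).

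In all, 1686 of 13837 genes were called at day 6 (limma, Benjamini-Hochberg adjusted p under 0.05), 775 higher and 911 lower with BMP4, of which 903 differed at least 2-fold. The 6 largest rises were Myl7 (6.53, adjusted p = 0.00163), the Schlafen gene Slfn2 (6.32), Hand1 (5.74), the calpain gene Capn6 (5.73), the growth factor gene Tgfb2 (5.64) and Id3 (5.58). The 6 largest falls were Chga, which encodes a secretory granule protein (-6.60), the protocadherin gene Pcdh8 (-6.36), Prrt1 (-5.32), Ripply2 (-5.14), Dll3 (-5.09) and the T-box gene Tbx22 (-4.95). Limma adjusted p of these 12 genes lay between 3.92e-05 and 0.00163. The rule that chose them required all 3 libraries of one group to lie above all 3 of the other. Mesp1 did not differ with BMP4 (-0.28 ± 0.26, adjusted p = 0.618).

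Of 18 tested BMP response genes, 12 rose, 1 fell and 5 were not called (16 and 1 when adjusted over the list alone), with a median log2 difference of 2.67. Id3 rose from 7.30 ± 4.55 (4.725 without early_SKM 3) to 364 ± 54.9 TPM, and Dlx3, a homeobox gene, was the member that fell (-1.07). The list passed camera (Benjamini-Hochberg adjusted p = 7.81e-13), with adjusted p = 0.106 with an estimated correlation. Of 15 cardiac transcription factors, 8 rose and none fell (11 adjusted over the list alone), among them Hand1, Nkx2-5 (from 0.310 ± 0.0656 to 25.2 ± 16.9 TPM, or 16.7 TPM without early_CM 1) and Gata4 (3.60 ± 1.45 to 64.7 ± 43.3 TPM) (camera adjusted p = 4.57e-08, and adjusted p = 0.247 with an estimated correlation). Of 22 cardiac contractile and calcium-handling genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone). Myl7 and Myl4 (6.50 ± 0.735 to 230.1 ± 128 TPM) rose, while Nppa, which encodes atrial natriuretic peptide, fell (-2.10). That list passed camera (adjusted p = 0.000131, and adjusted p = 0.727 with an estimated correlation). The library early_CM 3 stood apart in both cardiac lists. The median log2(TPM + 1) of the transcription factors was 5.59, 5.27 and 3.18 in early_CM 1, 2 and 3, against 1.08 to 1.501 in early_SKM. That of the contractile genes was 3.66, 3.86 and 2.51, against 2.34 to 2.445 in early_SKM, so the list median barely rose in early_CM 3. Among the 10 contractile genes at least 1 log2 unit higher in both other pairs, the rise in TPM in pair 3 was a median of 30.3% of theirs. It ran from -0.301% for Tnnt2 to 119.5% for Myh7.

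Of 14 paraxial and somitic mesoderm markers, 7 fell and none rose (10 falls adjusted over the list alone), Ripply2 and Dll3 among them, with a median log2 difference of -1.51 (camera adjusted p = 2.94e-08, and adjusted p = 0.188 with an estimated correlation). Of 14 immediate early and stress genes, 3 rose (5 adjusted over the list alone), among them the transcription factor genes Fos (2.11) and Atf3 (1.98) (camera adjusted p = 0.000285, and adjusted p = 0.106 with an estimated correlation). Within lists that did not pass camera, several regulators moved. Kdr, a VEGF receptor gene of early vascular and cardiac mesoderm, rose from 0.807 ± 0.793 to 33.1 ± 10.2 TPM. Isl1, a second heart field regulator, rose from 0.0800 ± 0.0458 to 22.9 ± 13.2 TPM. Lef1, a Wnt effector gene, fell from 113 ± 15.6 to 25.7 ± 7.88 TPM. Foxd3, a neural crest and pluripotency regulator, fell from 58.5 ± 8.71 to 5.78 ± 4.33 TPM (3.505 TPM without early_CM 3). Among endoderm and epithelial markers, 3 of 15 rose, such as the keratin genes Krt18 (2.99) and Krt19 (2.52) (camera adjusted p = 0.128). Neural markers had a median of -0.53, with camera adjusted p = 0.128 and adjusted p = 0.000253 with a replicate block within each day. Endothelial markers passed with that block (adjusted p = 0.0468 against 0.0580), with Kdr and Flt4 called of 14. Flt4 was lost without early_SKM 1, early_SKM 2, early_CM 1 or early_CM 2 (limma adjusted p from 0.0787 to 0.110). Proliferation genes had a median of 0.05 (camera adjusted p = 0.628), pluripotency markers of 0.15 (adjusted p = 0.572) and genes of constant use of -0.04 (adjusted p = 0.680). With the day 6 libraries alone and a replicate block, neural markers passed camera (adjusted p = 1.97e-05). Pluripotency, endothelial and atrial markers passed there as well (adjusted p = 0.0295 for each), with 4 pluripotency markers called higher. With an estimated correlation, tested without a block, none of these 4 lists passed (adjusted p = 0.727 for endothelial and adjusted p = 0.917 for the other lists).

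The count at day 6 rose to 2876 with the day 6 libraries alone, to 3194 with weights by day and to 3134 with a replicate block within each day, and limma called 1711 without the BMP4 libraries numbered 3 of both days. It was 935, 927, 929 and 927 without early_SKM 1, early_SKM 2, early_CM 1 or early_CM 2.

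**Figure D2:**
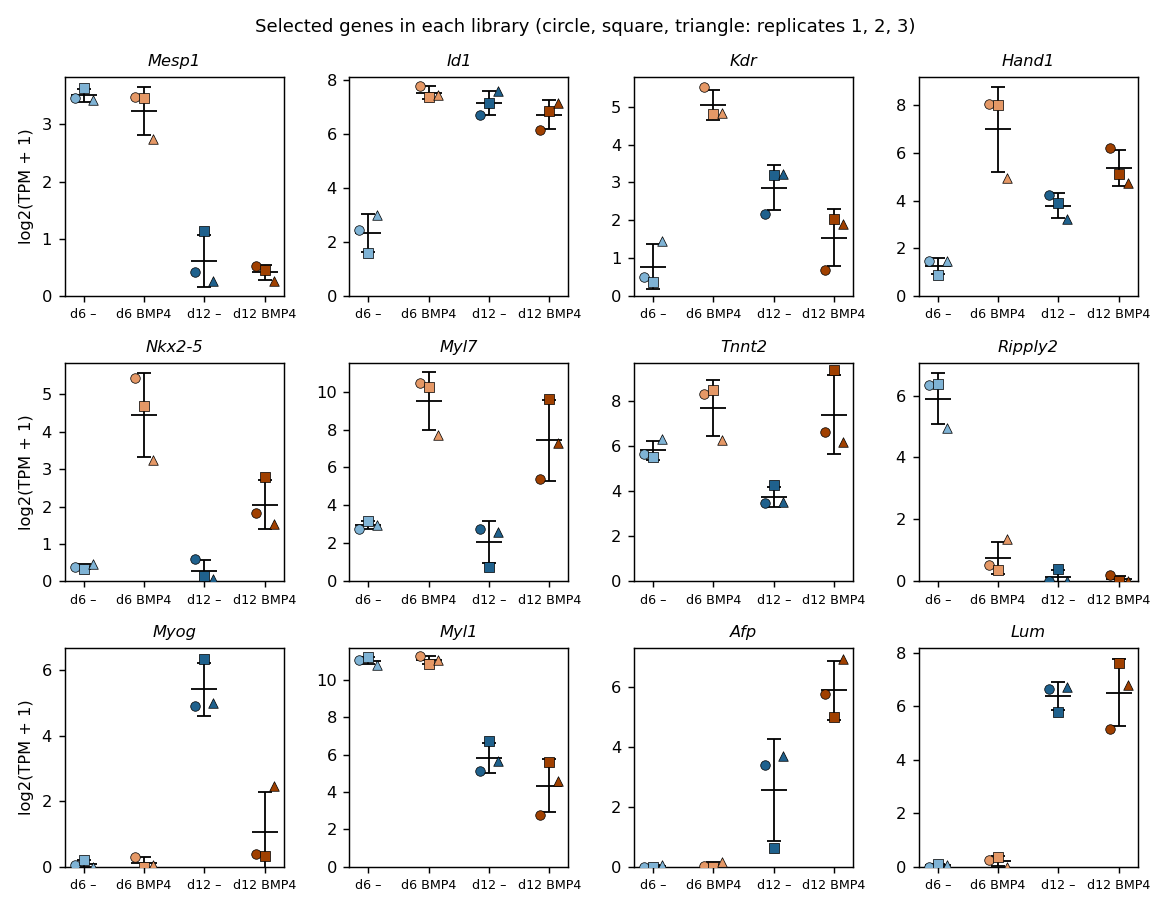
Expression of 12 genes as log2(TPM + 1) (vertical axis) in the 4 groups (horizontal axis), with a point per library and the mean ± SD of 3 libraries. Id1 was at 4.39 TPM on average in early_SKM and at 108 to 185 TPM in the other groups, and Myog was at 46.7 TPM in late_SKM and at 1.71 TPM in late_CM (0.290 TPM without late_CM 3).

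The second question was how the conditions differed at day 12, after continued culture with or without BMP4. Skeletal myogenic genes were lower with BMP4. The myogenic regulator genes Myog (chromosome 1, 134289989 to 134292548) and Myod1 (chromosome 7, 46376474 to 46379099) were at 46.7 ± 29.1 and 8.37 ± 3.58 TPM (mean ± SD, n = 3) without BMP4 and at 1.71 ± 2.46 and 0.503 ± 0.726 TPM with it. The embryonic myosin heavy chain gene Myh3 was at 19.3 ± 11.3 and 1.15 ± 0.875 TPM. Cardiac genes were higher with BMP4. Myl7 was at 3.86 ± 2.75 TPM without and 329 ± 406 TPM with BMP4. Tnnt2, which encodes cardiac troponin T (chromosome 1, 135836354 to 135852260), was at 12.8 ± 4.64 and 277 ± 336 TPM. Endoderm markers were higher as well, with Afp, the alpha-fetoprotein gene (chromosome 5, 90490737 to 90508907), at 7.34 ± 6.01 and 68.9 ± 47.7 TPM. Some means rested on 1 library. With BMP4, Myl7 was at 96.8 and Tnnt2 at 83.5 TPM without late_CM 2, Afp at 42.1 TPM without late_CM 3. Without BMP4, Myog was at 29.9 and Myh3 at 12.8 TPM without late_SKM 2. With BMP4 these genes were mostly in late_CM 3, as Myog was at 0.290 and Myh3 at 0.650 TPM without it, and Myod1 at 0.0400, 0.130 and 1.34 TPM in late_CM 1, 2 and 3.

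At day 12, 1332 genes were called (limma, Benjamini-Hochberg adjusted p under 0.05), 793 higher and 539 lower with BMP4, 574 of them at least 2-fold. More were lower than higher under quantile normalization (761 higher, 781 lower), without late_SKM 1 (594 and 658) and with a replicate block within each day (2076 and 2191). The 6 largest rises were Myl7 (5.38), the cardiac ankyrin repeat gene Ankrd1 (4.39), the small heat shock gene Hspb7 (4.11), Igfbp7, which encodes a secreted IGF-binding protein (3.89), Tnnt2 (3.64) and Afp (3.33). The 6 largest falls were Myog (-4.34 ± 0.53, limma adjusted p = 0.00538), the collagen gene Col26a1 (-3.49), Egfl6 (-3.44), Angptl1 (-3.31), Otor (-3.26) and the tendon gene Tnmd (-3.19). The limma adjusted p of these 12 lay between 0.00538 and 0.0316. That the 3 libraries of one group lay above the other 3 in all 12 was required by the rule that chose them. With a replicate block and the day 12 libraries alone, 8 of the 12 passed, the 12 lying at adjusted p from 0.0331 to 0.0613. With library weights by day, 7 of the 12 passed, and Myl7, Hspb7, Tnnt2, Afp and Col26a1 did not (limma adjusted p from 0.0510 to 0.0913). Myl7 and Tnnt2 were not called without late_SKM 2 (adjusted p = 0.0535 for each), nor Afp (adjusted p = 0.0576) or Angptl1 (adjusted p = 0.0635) without late_CM 1. Col26a1 was lost without any 1 of early_SKM 1, early_CM 1, late_SKM 2, late_SKM 3, late_CM 1 or late_CM 2 (adjusted p from 0.0508 to 0.0985).

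Of 22 cardiac contractile and calcium-handling genes, 8 rose and none fell at day 12 (12 and 1 adjusted over the list alone), with a median of 1.21 (camera, Benjamini-Hochberg adjusted p = 4.69e-05, and adjusted p = 0.399 with an estimated correlation). The rise was uneven between libraries. Tnnt2 was at 96.9, 665 and 70.0 TPM in late_CM 1, 2 and 3. The list's median log2(TPM + 1) was 2.77, 5.13 and 3.42, against 1.59 to 1.88 in late_SKM. Of 15 cardiac transcription factors, 5 rose (8 adjusted over the list alone; camera adjusted p = 0.000909, and adjusted p = 0.399 with an estimated correlation). Gata4 was at 10.9 ± 8.18 (6.22 without late_SKM 1) and 64.4 ± 27.5 TPM, but its call was lost without any 1 of early_SKM 1, early_SKM 3, late_SKM 2, late_SKM 3, late_CM 1 or late_CM 2 (adjusted p from 0.0536 to 0.112). Of 12 smooth muscle markers, 6 rose (7 adjusted over the list alone), such as the desmin gene Des (34.7 ± 5.07 to 163 ± 77.0 TPM) (camera adjusted p = 4.69e-05, and adjusted p = 0.399 with an estimated correlation). Oxidative phosphorylation and fatty acid oxidation genes shifted up by a median of 0.23, with 2 of 16 called (6 adjusted over the list alone), among them Cpt1b, which encodes a mitochondrial enzyme of fatty acid oxidation (1.05) (camera adjusted p = 0.00317, and adjusted p = 0.399 with an estimated correlation). With library weights by day all calls of contractile genes (Myl7 at limma adjusted p = 0.0624) and oxidative genes ended, and 1 transcription factor and 2 smooth muscle markers were called. With the day 12 libraries and a block, limma called 5 contractile genes higher and 1 lower, 6 transcription factors, 2 smooth muscle markers and 4 oxidative genes.

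Of 19 skeletal myogenic regulators and progenitor markers, 7 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -1.18 (camera, Benjamini-Hochberg adjusted p = 0.000126, and adjusted p = 0.399 with an estimated correlation). The progenitor genes Pax3 and Pax7 were not called (-1.47 ± 0.67, limma adjusted p = 0.181, and -1.18 ± 0.50, adjusted p = 0.150), but passed with a replicate block within each day (adjusted p = 0.0132 and adjusted p = 0.00799). Both also passed without late_CM 3 (adjusted p = 0.0405 and adjusted p = 0.0151). Their means rested largely on the libraries numbered 3. In late_SKM, Pax3 was at 13.3 TPM (6.75 without late_SKM 3) and Pax7 at 3.32 TPM (1.97 without it). In late_CM, Pax3 was at 4.41 TPM (1.57 without late_CM 3) and Pax7 at 1.10 TPM (0.11 without it). Of 19 skeletal contractile genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Myh3 (-3.17) and Mybph (-2.61) falling furthest (camera adjusted p = 0.00926, adjusted p = 0.399 with an estimated correlation and adjusted p = 0.0783 with a replicate block within each day). Retinoic acid pathway genes fell by a median of 1.31, with 4 of 12 called (5 adjusted over the list alone; camera adjusted p = 0.00373, and adjusted p = 0.399 with an estimated correlation). The calls of Crabp1 and Crabp2 were each lost without any 1 of 11 libraries (limma adjusted p up to 0.132 and 0.131). That of Aldh1a2 was lost without any 1 of 8 (adjusted p up to 0.116). Crabp1 was at 58.7, 52.5 and 1054 TPM in late_CM 1, 2 and 3. Anterior Hox genes fell by 1.31 in the median, with 3 of 11 called (4 adjusted over the list alone), such as Hoxb1 (12.5 ± 3.81 to 1.42 ± 0.850 TPM) (camera adjusted p = 0.00209, and adjusted p = 0.444 with an estimated correlation). With library weights by day the falls were 4 skeletal myogenic, 4 skeletal contractile, 1 retinoic acid and 1 Hox gene, and with the day 12 libraries and a block 9, 7, 5 and 5.

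Markers of other cell types moved in opposite directions at day 12. Of 15 endoderm and epithelial markers, 6 rose (10 adjusted over the list alone), with a median of 1.41, such as Afp and the apolipoprotein gene Apoa1 (7.40 ± 5.20, or 4.595 without late_SKM 1, to 46.8 ± 20.2 TPM) (camera, Benjamini-Hochberg adjusted p = 4.69e-05, and adjusted p = 0.399 with an estimated correlation). Of 15 neural markers, 2 fell (3 adjusted over the list alone), such as Sox3 (26.8 ± 9.28 to 8.85 ± 3.24 TPM; limma adjusted p = 0.0673 without late_CM 1), with a list median of -1.24. The neural list passed camera (adjusted p = 0.00151, adjusted p = 0.453 with an estimated correlation), but not without late_SKM 3 (adjusted p = 0.0889). Of 10 interferon response genes, 5 rose (8 adjusted over the list alone), such as Irf7 (1.10 ± 0.526 to 6.51 ± 3.91 TPM; limma adjusted p = 0.0628 without late_CM 1) (camera adjusted p = 4.69e-05, and adjusted p = 0.399 with an estimated correlation). Of 14 pluripotency markers, 2 rose (4 adjusted over the list alone), such as Dppa3 (33.5 ± 6.98 to 64.5 ± 15.9 TPM; limma adjusted p from 0.0584 to 0.0801 without late_SKM 1, late_SKM 2 or late_CM 1) (camera adjusted p = 0.000308, and adjusted p = 0.444 with an estimated correlation). With library weights by day limma called 2 endoderm markers, and all calls of the neural, interferon and pluripotency lists ended. With the day 12 libraries and a block it called 10 endoderm, 10 neural, 4 interferon and 10 pluripotency genes. Fibroblast and matrix genes had a median of 0.08 at day 12 (camera adjusted p = 0.869) and proliferation genes of -0.09 (adjusted p = 0.389).

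A further 5 lists passed camera at day 12 with adjusted p from 0.0358 to 0.0395 (from 0.399 to 0.505 with an estimated correlation). With a replicate block within each day, paraxial mesoderm markers (1 fall in 14, median -1.07) and immediate early genes (4 rises and 1 fall in 14, median 0.46) passed, at adjusted p = 0.0213 and adjusted p = 0.0182. Atrial and sinoatrial node markers (1 fall in 9), Wnt response genes (3 falls in 12, such as the stem cell receptor gene Lgr5 at -1.91) and primitive streak markers (none called of 13) did not (adjusted p = 0.0540, adjusted p = 0.155 and adjusted p = 0.0973). Each of the 5 was lost without 1 library or another. Paraxial markers were lost without late_SKM 3 or late_CM 1 (adjusted p from 0.0702 to 0.0889) and atrial markers without the same libraries (0.0826 to 0.169). Wnt genes were lost without late_SKM 1 or late_CM 2 (0.112 to 0.137). Without a single library the same held for streak markers without late_SKM 1, late_SKM 2, late_CM 2 or late_CM 3 (0.0672 to 0.154), and immediate early genes without late_SKM 1, late_SKM 2, late_CM 1 or late_CM 3 (0.0553 to 0.102). BMP response genes, with 2 rises in 18, did not differ as a list at day 12 (median -0.14, camera adjusted p = 0.921). Id1 was at 146 ± 44.8 and 108 ± 36.3 TPM (limma adjusted p = 0.459).

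How many genes differed at day 12 depended on the spread assumed. With the day 12 libraries alone limma called 0 genes (2533 at an unadjusted p under 0.05), and with library weights by day 135. It called 1554 with the day 12 libraries and a replicate block, 835 of them among the 1332, and 4267 with the block within each day. In simulated data the shared spread gave 26.3% false calls at day 12 without and 2.5005% with the pairing of same-numbered libraries. The block within each day gave 10.7% in the paired simulation. Only 100 genes were shifted by each size there, so these shares do not carry over to the 1332 genes called here. Limma called 353 genes without late_SKM 2, 318 without late_CM 1, 743 without early_SKM 1, 787 without early_CM 1 and 1614 without the BMP4 libraries numbered 3 of both days. Without all libraries numbered 1, 2 or 3 it called 0, 3 and 651.

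**Figure D3:**
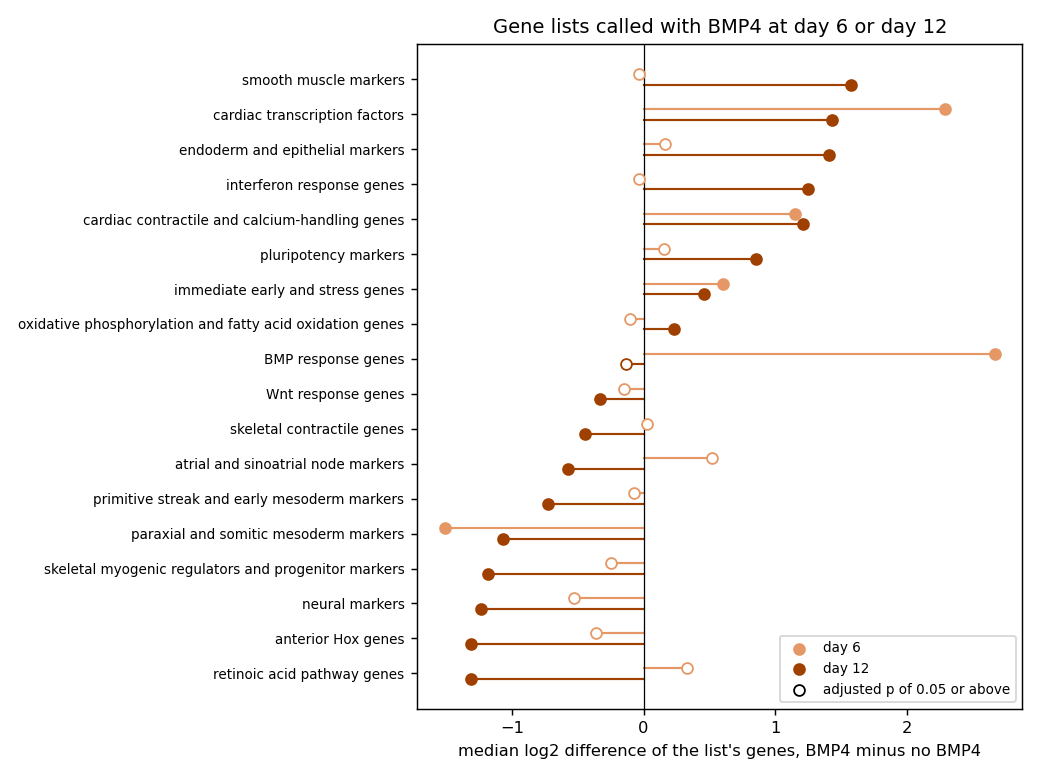
Median log2 difference (horizontal axis, BMP4 minus no BMP4) of each gene list that passed camera at day 6 or day 12, with lists on the vertical axis, colours for the days and open points where the adjusted p was 0.05 or above. The BMP response list stood at 2.67 with BMP4 at day 6 and at -0.14 at day 12.

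The next question was how the cells grown without BMP4 changed between day 6 and day 12. Myog went from 0.0700 ± 0.0819 to 46.7 ± 29.1 TPM (mean ± SD, n = 3), Myod1 from 0 ± 0 to 8.37 ± 3.58 TPM and Myh3 from 0.153 ± 0.0814 to 19.3 ± 11.3 TPM. Without late_SKM 2, Myog was at 29.9 and Myh3 at 12.8 TPM at day 12. The proteoglycan genes Lum and Dcn rose, from 0.0367 ± 0.0351 to 85.8 ± 27.5 TPM and from 0.143 ± 0.0929 to 111 ± 33.5 TPM. The cardiac actin gene Actc1 fell from 7694 ± 2100.3 to 98.4 ± 39.7 TPM. Tagln, a smooth muscle actin-binding gene, fell from 4394 ± 486 to 319 ± 146 TPM. Id1 rose from 4.39 ± 2.43 to 146 ± 44.8 TPM in cultures that had no added BMP4.

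Between the days without BMP4, 6007 genes were called (limma, Benjamini-Hochberg adjusted p under 0.05), 3366 higher and 2641 lower at day 12, 2395 of them at least 2-fold. More were lower than higher under quantile normalization (2795 higher, 3108 lower) and median-of-ratios scaling (3081 and 3127). The same held without late_SKM 2 (3040 and 3072) and without all libraries numbered 2 (2267 and 2467). The 6 largest rises were the collagen cross-linking gene Lox (6.60), Dcn (6.58), Emp1 (6.53), Mgp (6.52), Postn (6.42) and Lum (6.33). The 6 largest falls were the prostaglandin synthase gene Ptgds (-7.57), Chga (-7.21), Fbxl22 (-7.01), Tbx22 (-6.68), Rasgrp3 (-6.57) and Prrt1 (-6.45). Limma adjusted p of these 12 lay between 1.71e-07 and 0.000168.

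Of 20 proliferation genes, 19 rose and none fell (19 adjusted over the list alone), with a median of 1.05, such as the mitotic kinase genes Plk1 (1.38) and Aurkb (1.23) (camera adjusted p = 8.59e-09, and adjusted p = 0.507 with an estimated correlation). Of 14 hypoxia and glycolysis genes, 12 rose (12 adjusted over the list alone), such as Egln3, which encodes an oxygen sensor (2.59), and Adm (4.10) (camera adjusted p = 4.49e-05, and adjusted p = 0.507 with an estimated correlation). Of 15 endoderm and epithelial markers, 14 rose (15 adjusted over the list alone), such as the endoderm regulator Foxa2 (0.0667 ± 0.0351 to 14.5 ± 8.23 TPM) and Krt18 (2.89) (camera adjusted p = 4.49e-05, and adjusted p = 0.507 with an estimated correlation). Of 14 paraxial and somitic mesoderm markers, 1 rose and 11 fell (2 and 11 adjusted over the list alone), with a median of -3.09, the tendon regulator Scx rising (2.75) and Ripply1 (-6.31) and Ripply2 (-5.76) falling (camera adjusted p = 0.000140, and adjusted p = 0.507 with an estimated correlation). Of 18 BMP response genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 1.60 and Id3 at 7.30 ± 4.55 to 245 ± 99.9 TPM (camera adjusted p = 0.000585, and adjusted p = 0.507 with an estimated correlation). Of 12 smooth muscle markers, 8 fell (8 adjusted over the list alone), such as Tagln (-3.88) and Myh11 (-3.86) (camera adjusted p = 0.000653, and adjusted p = 0.507 with an estimated correlation). Fibroblast and matrix genes (8 rises and 1 fall in 15, 10 and 1 adjusted over the list alone) passed (camera adjusted p = 0.0160, and adjusted p = 0.637 with an estimated correlation). Endothelial markers (8 rises and 1 fall in 14, 10 and 1 adjusted over the list alone), such as the VEGF receptor gene Flt1 (1.94), passed as well (camera adjusted p = 0.0189, and adjusted p = 0.507 with an estimated correlation).

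Blood cell markers passed at camera adjusted p = 0.0387 (adjusted p = 0.507 with an estimated correlation), with all 5 called higher, such as the embryonic globin gene Hba-x (1.73), and did not pass without early_SKM 3 or late_SKM 1 (adjusted p from 0.0518 to 0.0749). Skeletal muscle lists went both ways. Of 19 skeletal contractile genes, 11 rose and 4 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.150), with Myh3 and Tnnt1 (3.43) among the rises and Myl1, a fast myosin light chain gene (-5.19), among the falls. Of 19 skeletal myogenic regulators, 9 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.232). Of 22 cardiac contractile genes, 6 rose and 7 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.402), with Casq2 (2.52) and Myl4 (2.10) higher and Actc1 (-6.31) and Myh7 (-5.59) lower. Of 12 retinoic acid pathway genes, 7 rose (7 and 1 adjusted over the list alone), such as Cyp26a1, which encodes a retinoic acid hydroxylase (3.28; camera adjusted p = 0.0906). No single library moved the count of genes by more than 1.5 times, and leaving out all libraries numbered 1 gave 3045.

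The same question was asked of the cells grown with BMP4. The endoderm genes Afp and Apoa1 rose, to 68.9 ± 47.7 and 46.8 ± 20.2 TPM at day 12 (mean ± SD, n = 3), with log2 differences of 5.83 and 5.32. Lum rose from 0.157 ± 0.146 to 112 ± 80.4 TPM and the elastin gene Eln from 0.590 ± 0.215 to 275 ± 352 TPM. The regulator genes Isl1 (from 22.9 ± 13.2 to 0.943 ± 0.182 TPM), Nkx2-5 (25.2 ± 16.9 to 3.44 ± 2.14 TPM) and Kdr (33.1 ± 10.2 to 2.14 ± 1.35 TPM) fell. Myl1 fell from 2161 ± 303 to 25.7 ± 21.1 TPM and Actc1 from 3897 ± 304 to 355 ± 444 TPM. Tcf21, a regulator of epicardial and pharyngeal mesoderm, rose from 0.187 ± 0.273 to 19.7 ± 26.2 TPM. Several day 12 means rested on late_CM 2. Without it Tcf21 was at 4.56, Eln at 74.4, Lum at 71.4, Actc1 at 98.4, Myl1 at 14.6 and Nkx2-5 at 2.22 TPM. Afp was at 42.1 TPM without late_CM 3, and Nkx2-5 at 16.7 TPM at day 6 without early_CM 1. Tnnt2 did not differ (-0.29 ± 0.77, limma adjusted p = 0.778).

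With BMP4, 6153 genes were called between the days (limma, Benjamini-Hochberg adjusted p under 0.05), 3477 higher and 2676 lower at day 12, 2335 of them at least 2-fold. Under quantile normalization 2788 were higher and 3328 lower. The 6 largest rises were Lox (6.69), Eln (6.31), Lum (6.30), Afp (5.83), Mgp (5.75) and the protease inhibitor gene Spink3 (5.60). The 6 largest falls were Myl1 (-6.73), the slow myosin heavy chain gene Myh7 (-6.26), Rasgrp3 (-5.71), Fbxl22 (-4.63), the arginase gene Arg1 (-4.61) and the chemokine gene Cxcl13 (-4.34). Limma adjusted p of these 12 lay between 7.23e-07 and 0.000467.

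Of 20 proliferation genes, 17 rose (18 adjusted over the list alone), with a median of 0.95, such as Plk1 (1.36) and the cyclin gene Ccnb2 (1.33) (camera adjusted p = 1.34e-07, and adjusted p = 0.616 with an estimated correlation). Of 15 endoderm and epithelial markers, 14 rose (15 adjusted over the list alone), with a median of 2.71 (camera adjusted p = 1.21e-06, and adjusted p = 0.616 with an estimated correlation). Of 14 hypoxia and glycolysis genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone), such as Egln3 (3.53) and the stress gene Ndrg1 (2.96) (camera adjusted p = 2.99e-05, and adjusted p = 0.616 with an estimated correlation). Of 10 interferon response genes, 9 rose (10 adjusted over the list alone), such as the antiviral genes Isg15 (0.540 ± 0.262 to 26.0 ± 16.4 TPM) and Bst2 (3.57) (camera adjusted p = 2.99e-05, and adjusted p = 0.616 with an estimated correlation). Of 14 pluripotency markers, 11 rose (12 adjusted over the list alone), such as Sox2 (1.02) (camera adjusted p = 0.00227, and adjusted p = 0.791 with an estimated correlation). Of 14 paraxial and somitic mesoderm markers, 1 rose and 5 fell (1 and 5 adjusted over the list alone), such as Foxc2 (-3.18) (camera adjusted p = 0.0211, and adjusted p = 0.791 with an estimated correlation).

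A further 4 lists passed camera with BMP4 between the days, at adjusted p from 0.0437 to 0.0477 (from 0.616 to 0.791 with an estimated correlation), and each was lost without 1 library or another. Second heart field and pharyngeal mesoderm regulators (4 rises and 8 falls in 17, 4 and 8 adjusted over the list alone), with Tcf21 (3.31) and Fgf8 (3.43) higher and Isl1 (-3.40) and Ebf3 (-3.36) lower, did not pass without late_SKM 3 or late_CM 2 (adjusted p from 0.0515 to 0.0621). Blood cell markers (3 rises in the 5 tested of 13 listed, 4 adjusted over the list alone), such as Runx1 (1.89), did not pass without early_CM 2 or late_SKM 2 (adjusted p from 0.0522 to 0.0548). Smooth muscle markers (1 rise and 7 falls in 12, 1 and 7 adjusted over the list alone), such as the calponin gene Cnn1 (-2.49) and Acta2 (-2.30), did not pass without early_CM 2, late_SKM 1, late_SKM 2, late_SKM 3, late_CM 1 or late_CM 3 (adjusted p from 0.0515 to 0.0995). Anterior Hox genes (5 falls in 11, 5 adjusted over the list alone), such as Hoxb1 (-2.83) and Hoxb3 (-2.68), did not pass without early_CM 2, late_SKM 1, late_SKM 2, late_SKM 3, late_CM 1 or late_CM 2 (adjusted p from 0.0588 to 0.0919). Of 18 BMP response genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.115). Cardiac transcription factors (2 rises and 5 falls in 15) did not pass either (camera adjusted p = 0.115), nor did fibroblast and matrix genes (6 rises and 1 fall in 15, median 0.27, adjusted p = 0.115). Cardiac contractile genes (5 rises and 7 falls in 22) did not pass (adjusted p = 0.295). The count of genes was 2634 without all libraries numbered 1.

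The last question was which effects of BMP4 differed between day 6 and day 12. The direct BMP targets Id1 and Id3 had log2 differences with BMP4 of 5.20 and 5.58 at day 6 and of -0.44 and -0.88 at day 12, where both groups expressed them. Kdr was higher with BMP4 at day 6 (4.28). At day 12 Kdr was not called, at 6.67 ± 2.74 TPM without and 2.14 ± 1.35 TPM with BMP4 (limma adjusted p = 0.0461 without late_SKM 1). Its effects differed by -5.61 ± 0.61 (SE; limma adjusted p = 0.000902). Ripply2 and Ripply1 were abundant only in early_SKM, and the effects of BMP4 on them differed between the days (differences of 5.07 ± 0.53 and 4.85 ± 0.34). Myog (-4.38 ± 0.75), Myod1 (-2.70 ± 0.46) and Myh3 (-3.14 ± 0.49) were near 0 in both groups at day 6 and lower with BMP4 at day 12.

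The interaction was called for 1140 genes (limma, Benjamini-Hochberg adjusted p under 0.05), 659 with a higher and 481 with a lower difference with BMP4 at day 12 than at day 6 (528 and 530 without late_SKM 1). The 4 highest among named loci were Chga (6.02), Prrt1 (5.08), Ripply2 (5.07) and Ripply1 (4.85), and the 4 lowest Capn6 (-6.64), Id3 (-6.46), Id2 (-6.00) and Id1 (-5.64), with limma adjusted p from 0.000118 to 0.00818. Of the 1140, 232 were higher and 398 lower with BMP4 at day 6 only, and 161 higher and 170 lower at day 12 only. Another 40 were lower at day 6 and higher at day 12, 23 the reverse, 5 higher and 2 lower at both days, and 109 were called at neither day. Across the BMP4 comparisons, 137 genes were higher at both days (44.4 expected if the calls were independent), 52 lower at both (35.5 expected) and 63 called in opposite directions. Of genes called with library weights by day, 21 were higher at both days (8.70 expected) and 4 lower at both (6.76 expected). Across the day comparisons, 2051 genes were higher with and without BMP4 (846 expected), 1449 lower (511 expected) and 136 opposite. The interaction count was 537, 653, 639 and 580 without early_SKM 1, early_SKM 2, early_CM 1 or early_CM 2, and 3538 with a replicate block within each day. Without all libraries numbered 1, 2 or 3 it was 1, 48 and 740.

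BMP response genes had the largest interaction as a list by camera p, with 9 of 18 lower and 1, Dlx3 (2.23), higher (1 and 11 adjusted over the list alone) and a median of -2.61 (camera adjusted p = 1.20e-08, and adjusted p = 0.385 with an estimated correlation). Interferon response genes (1 higher of 10, 5 and 0 adjusted over the list alone; median 1.34), with Usp18 called (3.64), passed (camera adjusted p = 0.00426, and adjusted p = 0.629 with an estimated correlation). Oxidative phosphorylation and fatty acid oxidation genes (3 higher of 16, 3 and 0 adjusted over the list alone), such as Cpt1b (1.65) and Cox7a1 (1.46), passed at the same level (adjusted p = 0.629 with an estimated correlation). Skeletal contractile genes (1 higher and 5 lower of 19, 1 and 7 adjusted over the list alone), such as Tnni1 (3.36) and Mybpc1 (-4.45), had a median of -1.29 (camera adjusted p = 0.00447, and adjusted p = 0.629 with an estimated correlation). Atrial and sinoatrial node markers (3 lower of 9, 1 and 4 adjusted over the list alone), such as Kcna5 (-3.34) and Gja5 (-1.73), passed (camera adjusted p = 0.00469, and adjusted p = 0.629 with an estimated correlation). Retinoic acid pathway genes (1 lower of 12, 0 and 3 adjusted over the list alone) passed (camera adjusted p = 0.00469, and adjusted p = 0.629 with an estimated correlation). Paraxial and somitic mesoderm markers (3 higher of 14, 6 and 1 adjusted over the list alone) had a median of 1.43 (camera adjusted p = 0.00469, and adjusted p = 0.629 with an estimated correlation). With a replicate block within each day it did not pass (adjusted p = 0.0594).

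Smooth muscle markers (1 higher of 12, 4 and 1 adjusted over the list alone) passed for the interaction (camera adjusted p = 0.0119, and adjusted p = 0.695 with an estimated correlation) but not without late_SKM 2 (adjusted p = 0.0588). Pluripotency markers (none of 14 called) passed (camera adjusted p = 0.0424, and adjusted p = 0.695 with an estimated correlation) but not without early_SKM 3, early_CM 2, late_SKM 2, late_SKM 3 or late_CM 1 (adjusted p from 0.0658 to 0.317). Second heart field and pharyngeal mesoderm regulators (4 lower of 17, 0 and 4 adjusted over the list alone), such as Isl1 (-4.07) and Tbx1 (-1.83), passed (camera adjusted p = 0.0424, and adjusted p = 0.629 with an estimated correlation) but not without early_CM 1, late_SKM 2, late_CM 1 or late_CM 2 (adjusted p from 0.0532 to 0.0747) or with a replicate block within each day (adjusted p = 0.141). With that block endoderm and epithelial markers (adjusted p = 0.0274, against 0.136 without it and 0.721 with an estimated correlation) also passed. The same held for neural markers (adjusted p = 0.0348, against 0.274 and 0.813).

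**Figure D4:**
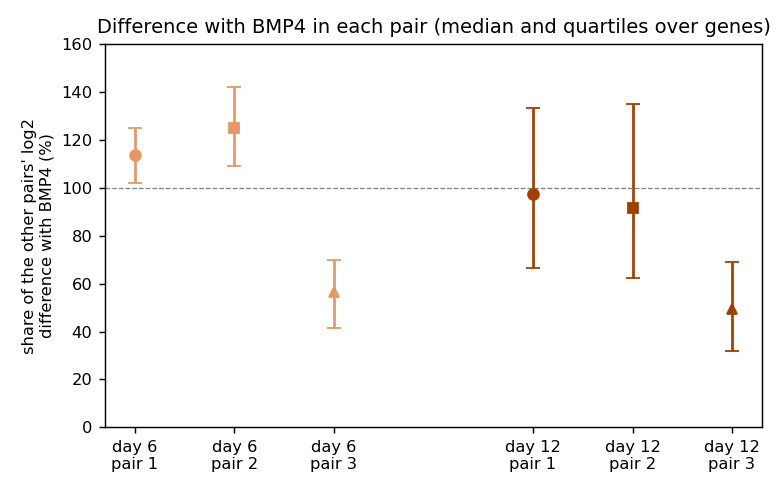
Difference with BMP4 in each same-numbered pair of libraries as a share (%, vertical axis) of the log2 difference in the other pairs, with pairs on the horizontal axis, points for the median over genes and bars for the quartiles. The pair numbered 3 lay at 56.3% at day 6 and at 49.3% at day 12.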

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

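In this part, the count over the 16 combinations that part every pair and the tests of scaling and of BMP ligands were chosen only after the results were seen. All results here drew attention because the difference with BMP4 at day 12 departed from that at day 6 in the interaction test. It was called for 1140 genes. The named genes with a lower difference at day 12 were Capn6 (-6.64), Id3 (-6.46), Id2 (-6.00), Id1 (-5.64), Kdr (-5.61), Myog (-4.38), Hand1 (-4.17), Isl1 (-4.07), Myh3 (-3.14), Myod1 (-2.70) and Tbx1 (-1.83). The call of Hand1 was lost without early_SKM 1, early_SKM 2, early_SKM 3, early_CM 1, early_CM 2, late_SKM 1 or late_SKM 2 (limma adjusted p from 0.0556 to 0.0776). Those with a higher difference were Chga (6.02), Prrt1 (5.08), Ripply2 (5.07) and Ripply1 (4.85). Among the lists, the median difference was -2.61 for BMP response genes, -1.56 for atrial and sinoatrial node markers, -1.29 for skeletal contractile genes, -1.23 for retinoic acid pathway genes and -0.41 for second heart field and pharyngeal mesoderm regulators. It was 1.43 for paraxial and somitic mesoderm markers, 1.34 for interferon response genes, 1.25 for smooth muscle markers, 0.71 for pluripotency markers and 0.28 for oxidative phosphorylation and fatty acid oxidation genes. None of these lists passed camera with an estimated correlation.

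For the interaction, 1 of the 16 combinations of splits that part all 3 pairs at each day gave as many called genes, the real one with 1140, and the highest other gave 349. These combinations are too few for a share under 0.05. Of all 100 combinations, most of which break the pairs, 1 gave as many and the highest other gave 801. The 9 other combinations that kept the real split at day 6 gave 238 to 801 genes, and those with another split at day 6 gave at most 1. For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split gave 1686 genes with BMP4 at day 6 (highest other 0), 1332 with BMP4 at day 12 (highest other 7), 6007 between the days without BMP4 (highest other 0) and 6153 between the days with BMP4 (highest other 9). In the BMP4 comparisons, where the numbers pair the libraries, the 3 other splits that also part 3 pairs gave 0 genes at both days, and the 6 that part 1 pair gave at most 0 at day 6 and 7 at day 12.

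BMP response genes were higher with BMP4 at day 6, and at day 12 the untreated cells expressed them as well. The scaling between libraries was argued against, since the lowest log2 difference of Id1, Id2 and Id3 from day 6 to day 12 without BMP4 was 4.20 under both other scalings. The median-of-ratios factors lay only between 0.957 and 1.10. That scaling could not have ended a rise of this size, so its outcome was fixed in advance. A candidate explanation is that the untreated cultures made BMP ligands of their own, and 4 of 5 ligand genes were called higher at day 12 than at day 6 without BMP4. Bmp4 went from 4.99 ± 2.01 to 80.1 ± 3.85 TPM (limma adjusted p = 0.000125), Bmp2 rose by 1.60, Bmp5 by 2.83 and Bmp7 by 2.08, while Bmp6 was not called (0.49, adjusted p = 0.405). Ligand transcripts do not measure signalling, so the explanation stays a hypothesis, and protein was not analysed here.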

How the results depend on the processing

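Library weights by day, the replicate block within each day, fits on the libraries of 1 comparison with a block, and fits without the BMP4 libraries numbered 3 were chosen only after the data were seen. Differences that were not called did not all keep their sign, as that of Tnnt2 between the days with BMP4 turned positive without late_CM 3. The balance of higher and lower genes reversed in 4 comparisons. With BMP4 at day 12 it did under quantile normalization (761 and 781), without late_SKM 1 (594 and 658) and with the block within each day (2076 and 2191), and between the days without BMP4 under median of ratios (3081 and 3127), quantile normalization (2795 and 3108), without late_SKM 2 (3040 and 3072) and without replicate 2 (2267 and 2467). With BMP4 it did under quantile normalization (2788 and 3328), and for the interaction without late_SKM 1 (528 and 530) and replicate 1 (0 and 1). Of the counts, 251 stayed within 1.5 times, 38 were smaller and 10 larger. Of the list results, 1212 kept their side of the threshold and 175 did not, and of the named-gene results 10276 kept it, 1207 lost and 88 gained a call. Most of the losses came with fewer libraries, 198 without replicate 1 and 162 without replicate 2. Otherwise the cause was not tested.

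With BMP4 at day 6 (1686 genes), the count was 2876 with only the groups of the comparison, 3861 with these and a replicate block, 3194 with weights by day, 3134 with the block within each day and 903 at a log2 difference of at least 1. With BMP4 at day 12 (1332), limma called 0 with only the groups of the comparison (2533 at an unadjusted p under 0.05), 135 with weights by day, 4267 with the block within each day and 574 at a log2 difference of at least 1. The last setting gave 2395 without and 2335 with BMP4 between the days. The interaction (1140) was 3538 with the block within each day. Leaving out libraries or replicate numbers gave 293 to 1847 genes with BMP4 at day 6, 0 to 1851 at day 12 (without replicate 1: 0 by limma, 2208 at an unadjusted p under 0.05), 3045 to 6320 and 2634 to 6493 between the days without and with BMP4, and 1 to 1340 for the interaction.

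With an estimated correlation camera called 0 lists in each comparison, against 5 with BMP4 at day 6, 17 at day 12, 9 and 10 between the days and 10 for the interaction. Fry called 11 at day 12, 15 between the days without BMP4 and 4 for the interaction. At day 6 camera called 8 lists with only the groups of the comparison and 9 with these and a block. Leaving out libraries gave 5 to 6 lists at day 6, 15 to 20 at day 12, 8 to 12 and 7 to 14 between the days, and 8 to 13 for the interaction. Genes called the same way in both BMP4 comparisons (189) were 400 with only the groups and a block, 25 with weights by day (4 of them lower, 6.76 expected), 92 at a log2 difference of at least 1 and 165 without replicate 3. Those in both day comparisons (3500) were 1128 at a log2 difference of at least 1 and 2336 without replicate 3. Same-numbered libraries of different days did not deviate together (r across genes from -0.284 to 0.174), so the day comparisons were not paired. Depth is unknown for this unit, so no limit from depth can be given.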

Other observations

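In this part, the tests of the libraries numbered 3 and those of explanations for the endoderm markers were chosen only after the results were seen. The muscle genes Acta2 and Myocd fell from day 6 to day 12 with and without BMP4. Acta2 was at 9434 ± 1512 and 9609 ± 756 TPM at day 6 and at 659.7 ± 86.5 and 2272 ± 1606 TPM at day 12 (without and with BMP4, mean ± SD, n = 3). Myocd, a coactivator of smooth and cardiac muscle genes, was at 121 ± 8.53 and 86.1 ± 11.2 TPM at day 6 and at 0.913 ± 0.536 and 6.46 ± 6.76 TPM at day 12. Without late_CM 2 the day 12 means with BMP4 were 1349 TPM for Acta2 and 2.58 TPM for Myocd. Of the genes of constant use, Hprt fell between the days by 2.16 log2 units without and 2.10 with BMP4, and Actb by 1.04 and 0.69, while Pgk1 rose by 1.40 and 1.30.

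The libraries with BMP4 numbered 3 lay closer to the untreated ones, as their pair showed 56.3% of the other pairs' difference at day 6 and 49.3% at day 12. An exchange of the libraries numbered 3 within a day was argued against, since the untreated library lay at a median position of 0.110 (quartiles 0.0222 to 0.229) at day 6 and -0.0163 (-0.268 to 0.192) at day 12, where 0 is the other untreated and 1 the other BMP4 libraries. An untreated library with a wrong label was argued against for early_CM 3, at 0.698 against 0.110 at most in the untreated libraries. For late_CM 3 the position of 0.4505 (against 0.398) left it open. A second bound, on the cardiac lists, was added only after that. The medians of both lists in late_CM 3 lay above the untreated ones by 5.32 times the range of these 3 libraries. In early_CM 3 the same measure was 4.04 for the transcription factors and 0.580 for the contractile genes. A bound added in this way does not settle the label of late_CM 3. A weaker response of the BMP4 cultures numbered 3 was not tested and stays open. RNA of untreated cells in early_CM 3 as the whole cause stays open. The cardiac transcription factors had a median linear share of 16.7%, outside that of random lists (23.4% to 60.2%). Those lists drew genes independently, so their range may be too narrow for genes that move together, and this test cannot exclude the cause. The cardiac contractile genes (30.3%) lay within the range of their random lists (22.4% to 60.05%). For the BMP response genes the quartile range over the median was 2.68 times the larger in the other pairs, above the bound of 1.5 set for it. That decides nothing, since the ranges alone were alike (54.4 points against 50.2 and 50.9) and the genes were not chosen alike.

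Endoderm and epithelial markers were higher with BMP4 at day 12, with a list median of 1.41. A lower share of mesodermal cells would by itself raise other cell types alike. The endoderm median exceeded the neural median by at least 2.32 log2 units in each of the 3 pairs, so endoderm and neural markers were not raised alike. Both list medians were known when this comparison was chosen, and a separate fall of neural markers could hide such a change. A lower share of mesodermal cells therefore stays open. The scaling between libraries was argued against, with a lowest list median of 1.41 under the other scalings. With median-of-ratios factors of only 0.957 to 1.10, that scaling could hardly have moved the list median. These lists hold a few genes each, so a change in the number of endodermal cells may be a candidate explanation that counts of cells would test.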
